A study of Drosophila melanogaster with 16 samples.

How the data were processed

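Nuclei from 50 mg of fly heads per replicate were digested with micrococcal nuclease and briefly sonicated, and chromatin was precipitated with antibodies against H3K4me1 or H3K27ac, per the labels' protocols. A part of each chromatin extract was kept as input. The labels name 2 ChIP and 2 input replicates for each mark at day 10 and at day 50, 16 samples in all. The deposited peak lists number 4, 1 for each mark and age, and the names of their peaks show that both replicates were pooled before peaks were called. No list of a single replicate and no read count was used here, so the spread between replicates and the depth of the libraries are unknown, and an interval given for a share covers counting error only.

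The submitters' processing notes name FastQC, Trim Galore, STAR 2.5.3a, MACS2 2.1.1 and deepTools, with no role or order, and the genome build BDGP6. Further settings are not given in the sources used here, apart from the word nomodel in the peak names. In the deposited lists every peak was at least 147 bp wide and had a -log10 q of at least 1.30. Column 7 of the deposited lists was taken as the fold enrichment over the local background that the authors' peak caller reports. Their -log10 p and -log10 q values per peak were likewise deposited by the authors. The summit offset, a number of bases from the start of each peak, was also deposited by the authors and was not needed for a printed value. Fold and -log10 q were used only to describe, rank or filter peaks within a list. A threshold on q admits more peaks in a deeper library, so the number and length of peaks can differ between ages for that reason alone, and nuclease digestion favours accessible chromatin and fragments of nucleosome size.

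Peaks on 2L, 2R, 3L, 3R, 4, X and Y were analysed, and those on other sequences are reported apart. Gene positions came from a RefSeq table of the Release 6 assembly, to which BDGP6 corresponds, and on 2L, for example, the highest peak end (23313571) was near the highest gene end (23313578). On 2R, 4 and X some peaks lay beyond the last gene, and on Y the last peak ended at 2484739, well before the last gene (3666928). That table gives the start and end of 13946 protein-coding genes on these sequences but neither strand nor exons, so promoters, exons, introns and untranslated regions could not be told apart. For this reason the promoter window fixed beforehand, 500 bp on each side of a transcription start, was replaced by 500 bp on each side of both gene ends. The gene region was the gene body with 1000 bp on both sides in place of the upstream side alone. Distal peaks lay more than 1000 bp from any gene end, which includes starts of shorter transcripts inside genes.

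A peak was shared if it overlapped a peak of the other list by at least 1 base. Shares have exact (Clopper-Pearson) 95% intervals and were set beside 1000 random placements of the same peaks within their chromosomes. For each gene and mark the bases of its region under peaks were counted at each age. Neighbouring or nested genes share peaks where their regions overlap. For 19 gene lists fixed before the data were examined, the median and the mean of the difference, day 50 minus day 10, in the percent of the region under peaks were placed among 10000 random lists. These had the same size and were matched on mean percent covered (10 bins) and region length (3 bins). The lists were phototransduction, synapse and neuronal excitability, neuronal surface recognition, glia, fat body, muscle, hemocyte, testis and germline, chemosensory receptors, Hox and segmentation, innate immunity, heat shock and chaperones, oxidative stress and detoxification, circadian clock, insulin, TOR and lifespan, oxidative phosphorylation, cytosolic ribosomal proteins, chromatin modifiers, and autophagy. Of the 38 pairs of list and mark, 7 medians and 10 means lay outside percentiles 2.5 to 97.5. By chance about 1.9 would, if percentiles were spread evenly. That does not hold for medians, of which 0% lay outside for unchanged simulated lists. The simulation removed peaks whatever their strength and drew only genes with a peak, so its rates need not hold for the real lists. The means were chosen after seeing the data, so their count was not set beforehand. Symbols of the lists that were absent from the gene table and left out were CG9657, apoltp, Unc-89, nos, Rye, Hsp67Bb, Trxr-1, Trx-2, Jafrac1, Jafrac2, Tor, sesn, lid and Vps34. The symbol sesn was a second spelling of Sesn, which was present and used. A percentile describes these lists of peaks and is not a test of age. Members of gene clusters lie side by side and share peaks, which the random lists do not imitate.

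Named genes followed a rule fixed at the same time. For each mark these were the 8 genes with the largest excess of covered bases at each age, leaving out overlapping regions, and the 5 gene ends at each age with the highest fold among those with a peak at that age only. Up to 4 members of each list with the largest absolute difference in percent covered were added, then trr, Lpt, Utx and nej, and the genes nearest to the 5 distal H3K27ac peaks of the highest fold at each age. Alternatives tried were peaks of -log10 q of at least 5, the upper 50% of each list, equal numbers of peaks, merging of peaks less than 500 bp apart, an overlap of at least 50% of the peak, windows of 250 and 1000 bp, and other gene regions.

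Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Interval functions were tested on simulated data against base-by-base counting. The list statistic was tested on each day 10 list thinned at random to 90% of its peaks for each of 2 simulated ages, over 13946 genes. Unchanged lists, 200 of 30 genes each, were drawn from genes with a peak. Their mean lay outside the random range for 3.5% (H3K4me1) and 6.5% (H3K27ac), and their median for 0%. When 20% of the peaks of a list's regions were removed at the second age, the mean of 78% and 68% of 50 lists and the median of 80% and 42% lay below the range, and when 40% were removed all did.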

Results

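The series profiled 2 histone marks in heads of male w1118 flies (*Drosophila melanogaster*; w1118 is a common white-eyed laboratory strain) at day 10 and day 50 of adult life, as young and old adults. Monomethylation of histone H3 at lysine 4 (H3K4me1) is found at enhancers and within transcribed genes, and acetylation of lysine 27 (H3K27ac) marks active promoters and enhancers. The 16 samples formed 8 groups of 2: a chromatin immunoprecipitation (ChIP) and an input group for each mark at each age. The values came from 4 peak lists, 1 for each mark and age, each made from both ChIP replicates together. With 1 list per mark and age there was no spread between replicates and no test of age, so every difference between days is a difference between 2 lists. Read depth was unknown.

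H3K4me1 had 43871 peaks at day 10 and 41851 at day 50, and H3K27ac had 26699 and 25439. On the 7 main sequences (2L, 2R, 3L, 3R, 4, X and Y), H3K4me1 peaks covered 17.9 Mb at day 10 and 17.3 Mb at day 50, with median widths of 296 and 295 bp. H3K27ac peaks covered 9.19 and 8.95 Mb, with median widths of 280 and 285 bp. The authors' fold enrichment over background had a median of 2.53 and 2.58 in the H3K4me1 lists and of 2.49 and 2.61 in the H3K27ac lists.

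For H3K4me1, the 8 gene regions with the largest excess of covered bases at day 10 were 46.6 to 283 kb long. The region of sif, which encodes a Rac exchange factor of synapses, had 24.1 kb under peaks at day 10 and 16.1 kb at day 50. The microtubule-binding futsch had 14.9 and 9.03 kb, the Shaker potassium channel gene Sh 14.0 and 8.45 kb, and the RNA-binding bru3 16.7 and 11.2 kb. Mur2B (26.8 and 19.1 kb), CG43867 (19.0 and 12.5 kb), the GDNF receptor-like Gfrl (13.6 and 7.33 kb) and the dioxygenase gene Tet (28.0 and 21.9 kb) completed the 8 genes taken by the naming rule. In the other direction stood regions of 10.7 to 30.6 kb. That of mv, the LYST homologue of lysosome-related organelles, had 1.09 kb under peaks at day 10 and 5.76 kb at day 50. Bruce, an inhibitor of apoptosis with a ubiquitin-conjugating domain, had 8.72 and 12.7 kb, dikar 3.75 and 7.59 kb, poe 9.75 and 13.4 kb, the deubiquitinase gene puf 7.95 and 11.4 kb, CG8677 2.57 and 5.96 kb, the synaptic vesicle gene tweek 7.18 and 10.6 kb, and Dlg5 0.71 and 4.03 kb.

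Over all 13946 protein-coding genes, the H3K4me1-covered share of the region (gene body and 1000 bp on both sides) was higher at day 50 for 5508 genes and lower for 5114, with a mean difference of 0.707 percentage points. The excess of higher genes depended on the setting: with the upper 50% of each list by -log10 q there were 4479 higher and 4713 lower, and with gene bodies alone 4534 and 4595. A peak lay within 500 bp of a gene end at both ages for 7519 genes, at day 10 only for 569 and at day 50 only for 730. The day 10 only ends with the highest peak folds belonged to Tnpo (4.77), RAF2 (4.26), Bruce (4.26), ymp (4.14) and Psi (4.11). Those seen at day 50 only belonged to Mkrn1 (4.77), the amino acid transporter gene mnd (4.12), CRMP (4.10), and CG7694 and fray, which share a peak of 4.05. These calls concern the 500 bp windows alone. In the whole region, Tnpo had 3.551 and 3.01 kb under peaks at days 10 and 50, RAF2 2.032 and 2.272 kb and Bruce 8.719 and 12.67 kb. The values were 1.297 and 0.857 kb for ymp, 3.2 and 2.992 kb for Psi and 1.243 and 1.237 kb for Mkrn1. They were 1.514 and 1.447 kb for mnd, 4.204 and 4.588 kb for CRMP, and 2.09 and 2.966 kb for both CG7694 and fray.

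Synapse and surface recognition genes stood below their matched random lists in H3K4me1. Of 51 genes of neuronal surface recognition, 45 had a lower share under peaks at day 50 and 5 a higher one, with a mean difference of -2.86 percentage points and a median of -2.31, both below all 10000 random lists. The median was -0.525 in windows of 1000 bp at the gene ends (percentile 0.16) and -0.911 with the upper 50% of each list, where the mean was -1.75 (percentile 0.12). The share at dpr14 was 26.3% at day 10 and 13.3% at day 50, at DIP-delta 12.5% and 3.21%, at dpr5 21.4% and 13.7%, and at dpr9 10.0% and 2.35%; these encode immunoglobulin-domain proteins of synaptic partner recognition. Of 32 genes of synapse and neuronal excitability, 22 were lower and 10 higher, with a median difference of -1.90 (percentile 0.56) and a mean of -2.22 (percentile 0.17). Examples were futsch (31.9% and 19.4%), the synaptic vesicle genes nSyb (53.6% and 44.2%) and Rab3 (37.9% and 31.0%), and Gad1, which makes the transmitter GABA (15.7% and 6.64%). In windows of 1000 bp on each side of the gene ends the synapse list had a median of 0.175, at percentile 77.6, so its difference lay outside those windows. With random lists matched in 20 bins of region length, the synapse mean was at percentile 0.69 and its median at 1.48. Surface recognition stayed below all of these lists, but their mean was -1.01, against -0.275 with 3 bins. Phototransduction genes had 15 of 24 lower and 7 higher, with a median of -1.11 just inside the random range (percentile 2.75). Their mean of -0.682 was well inside it (percentile 16.0). Among them inaC had 24.7% and 14.3%, trp 21.7% and 13.1%, Rh4 13.1% and 20.7%, and ninaA 16.4% and 40.1%.

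The fat body list stood at the opposite end. Of its 17 genes, 11 had a higher H3K4me1 share at day 50 and 0 a lower one, and 6 had no peak at either age. The median difference was 3.53 (percentile 99.9) and the mean 5.56, above all 10000 random lists. With only peaks of -log10 q of at least 5 or with gene bodies alone the median was 0, and with the upper 50% of each list the mean was 1.90, inside the range (percentile 84.5). The lipid droplet gene Lsd-1 had 10.3% at day 10 and 35.1% at day 50, the fatty acid synthase gene FASN1 28.1% and 49.7%, the lipid transfer gene Mtp 21.8% and 30.8%, and the lipase gene bmm 22.1% and 30.6%. Genes of oxidative stress and detoxification had 18 of 28 higher and 9 lower, with a median of 2.90 (percentile 99.0) and a mean of 2.74 inside the random range (percentile 94.1). The glutathione transferase genes GstE1 (10.9% and 44.9%) and GstD2 (10.2% and 23.5%) and the P450 gene Cyp6a2 (10.4% and 23.1%) were higher at day 50, while the peroxiredoxin gene Prx3 was lower (60.9% and 35.5%). That median was inside the random range under every other setting but equal numbers of peaks.

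Cytosolic ribosomal protein genes had lower H3K4me1 shares for 50 of 86 and higher ones for 32, with a median of -1.25 (percentile 0.20) and a mean of -1.73 (percentile 0.03). RpS28a had 28.8% and 11.8%, RpL36 23.3% and 9.0%, RpS24 26.1% and 13.6%, and RpS5b, in the other direction, 15.2% and 29.9%. With -log10 q of at least 5 the median was 0, at percentile 41.0, and with the upper 50% of each list the mean was -0.705, at percentile 11.6. Oxidative phosphorylation genes had 43 of 80 lower and 30 higher, and only their mean of -1.10 lay below the random lists (percentile 0.65), with ND-18 at 30.6% and 16.8% and ND-SGDH at 19.0% and 6.54%. COX4L, the member with the largest difference, went the other way, from no peak to 19.8%, and with gene bodies alone the mean of -1.35 lay inside the range (percentile 7.22).

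The other 12 lists lay inside the range of their random lists for H3K4me1. Higher and lower genes numbered 6 and 6 for glia, 9 and 4 for muscle, 5 and 4 for hemocyte, 11 and 7 for testis and germline, 31 and 35 for chemosensory receptors, 10 and 11 for Hox and segmentation, and 17 and 11 for innate immunity. They numbered 12 and 8 for heat shock and chaperones, 10 and 8 for circadian clock, 13 and 12 for insulin, TOR and lifespan, 20 and 15 for chromatin modifiers, and 12 and 12 for autophagy. Of the 180 chemosensory genes, 114 had no H3K4me1 peak at either age, which fixed the median of that list at 0. Single members still differed, such as the immune transcription factor gene Rel (57.6% and 72.2%), the photoreceptor gene of the clock cry (31.2% and 18.1%), bgcn (14.9% and 29.8%), Hsp70Aa (5.02% and 17.8%) and Atg101 (15.9% and 34.4%). For circadian clock genes the median was 0.537 and the mean -0.216, and for autophagy 0.0584 and -0.321, so these statistics differed in sign.

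**Figure D1:**
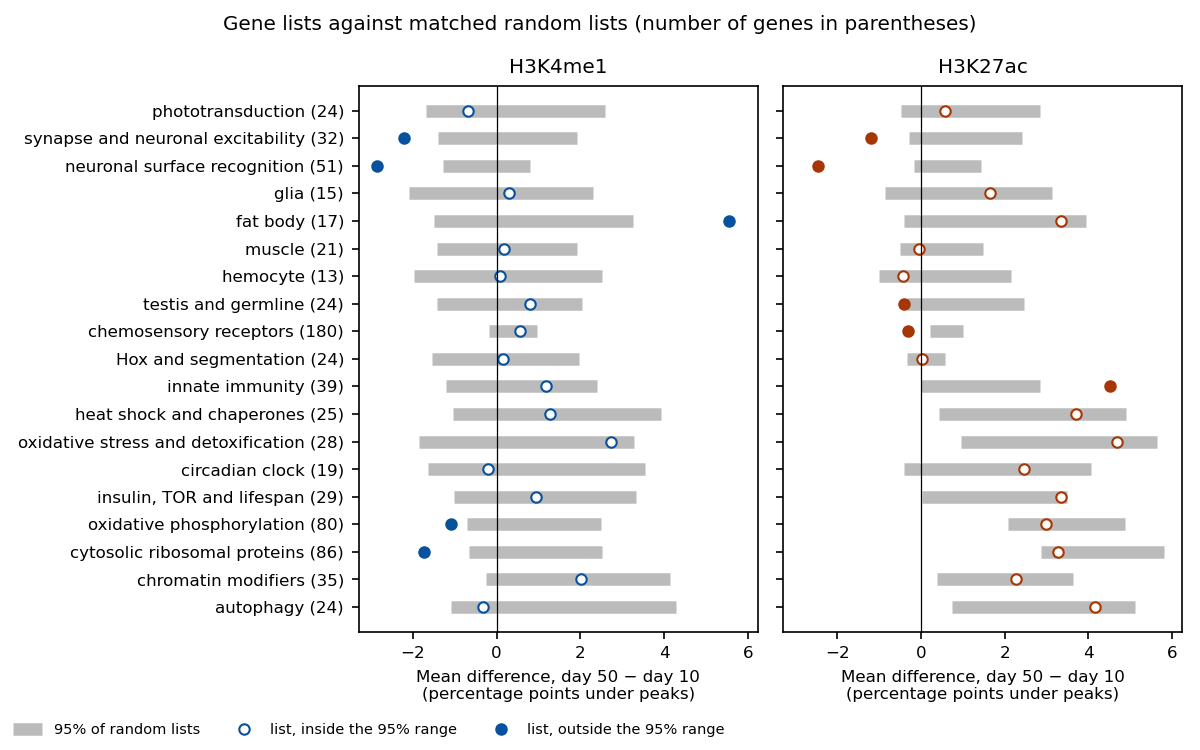
Mean difference between day 50 and day 10 in the percent of the gene region under peaks (percentage points, x axis) for each of 19 gene lists, for H3K4me1 and H3K27ac; grey bars span 95% of 10000 matched random lists and filled points lie outside that range. Neuronal surface recognition lies at -2.86 and -2.47, and fat body at 5.56 for H3K4me1. The random lists shown were matched in 3 bins of region length.

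For H3K27ac, the 8 gene regions with the largest excess at day 10 were 58.1 to 181 kb long. The region of Rbp6, an RNA-binding gene of the Musashi family, had 38.8 kb under peaks at day 10 and 21.7 kb at day 50, with 125 and 83 peaks. The surface recognition gene dpr12 had 21.2 and 10.7 kb, the axon guidance gene Sema1a 17.3 and 9.0 kb, CG43867 27.3 and 19.0 kb, the glucose transporter gene Glut1 12.2 and 4.21 kb, the growth factor gene Pvf3 9.09 and 1.85 kb, CG42238 14.3 and 7.21 kb, and Tet 28.6 and 21.8 kb. The largest excess at day 50 was at hth, a homeodomain transcription factor gene, with 6.35 and 10.3 kb and 28 and 37 peaks. It was followed by CG46429 (7.10 and 10.2 kb), whose region overlaps that of the stress-induced Sesn, then by e(y)3 (2.50 and 5.02 kb), the nuclear receptor gene svp (2.68 and 5.17 kb), cnc, the fly homologue of Nrf2 (3.27 and 5.57 kb), the insulin pathway kinase gene Pdk1 (5.57 and 7.78 kb), emp (2.85 and 5.05 kb) and CG34310 (2.37 and 4.48 kb).

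**Figure D2:**
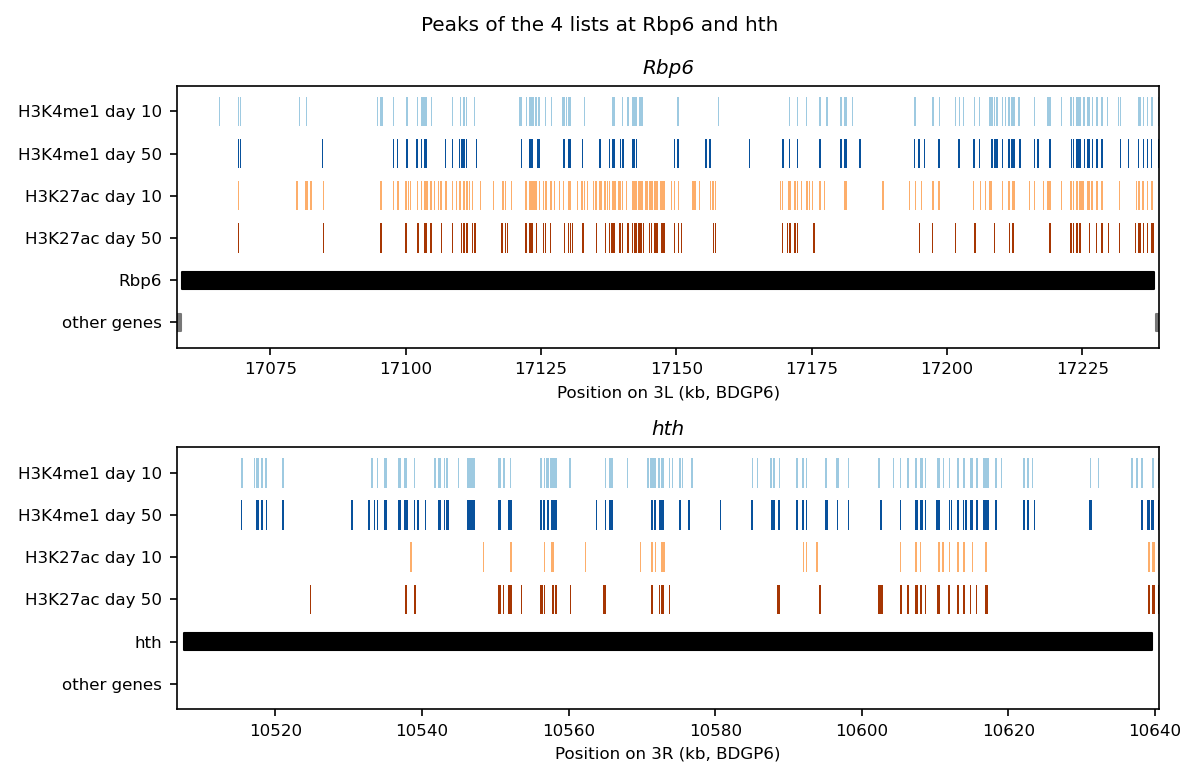
Positions of the peaks of the 4 lists (rows) along Rbp6 on 3L and hth on 3R (x axis, kb in BDGP6), with the annotated genes as black and grey bars. Over Rbp6 the H3K27ac list has 125 peaks at day 10 and 83 at day 50, and over hth 28 and 37.

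H3K27ac covered a higher share of the region at day 50 for 6570 genes and a lower one for 2575, with a mean difference of 1.79 percentage points, although its whole list covered fewer bases at day 50. The whole list covered more bases at day 50 with -log10 q of at least 5 and with equal numbers of peaks. A peak lay within 500 bp of a gene end at both ages for 7276 genes, at day 10 only for 234 and at day 50 only for 559. The day 10 only ends with the highest folds were those of Lis-1 (4.51), the receptor gene Notch (N, 3.79), CG8093 (3.69), CG13326 (3.62) and the receptor gene Egfr (3.57). At day 50 only they were those of CG14020 (4.78), CG34409 (4.49), CG32633 (4.12), CG4945 (3.98) and CG34310 (3.94). These calls concern the 500 bp windows and not the whole gene region. Under peaks at days 10 and 50, the region of Lis-1 had 2.181 and 2.134 kb and that of N 0.31 and 0.265 kb. CG13326 had 0.617 and 0.642 kb, CG8093 0.597 and 0.766 kb and Egfr 1.145 and 2.334 kb. Of the day 50 only regions, CG32633 had 0.45 and 0.43 kb, CG34409 0.489 and 0.505 kb and CG4945 0.492 and 0.523 kb. CG14020 had 0.314 and 0.429 kb and CG34310 2.366 and 4.482 kb.

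Synapse and surface recognition genes were again below their random lists. Of the surface recognition genes, 32 had a lower H3K27ac share at day 50 and 10 a higher one, with a median of -0.576 and a mean of -2.47, both below all 10000 random lists. The median was 0 and inside the range with the upper 50% of each list (percentile 50.0) and in the 1000 bp windows at gene ends (percentile 26.0), and the mean was -1.14 and -0.182 there, the latter at percentile 0.03. dpr12 had 36.5% at day 10 and 18.4% at day 50, dpr9 22% and 5.54%, Dscam4 27.7% and 16.0%, and Dscam2 18.8% and 8.34%. The synapse list had 22 lower and 7 higher, with a median of -1.19 and a negative mean, each at percentile 0.01. The median was closer to 0 with -log10 q of at least 5 (-0.400, percentile 0.04) and in the 1000 bp windows at gene ends (-0.025, percentile 0.02), where the mean was -0.279 (percentile 0.07). The vesicle fusion gene Syx1A had 35.8% and 22.2%, the GABA receptor gene Rdl 10.3% and 4.93%, futsch 35.9% and 30.2%, and comt, in the other direction, 9.22% and 17.2%. With random lists matched in 20 bins of region length, the H3K27ac mean of the synapse list was at percentile 1.74 and that of surface recognition still below all of them. Means of chemosensory receptors (-0.298, below all 10000) and of testis and germline genes (-0.397, percentile 2.14) were also low, although 22 against 17 and 7 against 4 members had the higher share at day 50. No H3K27ac peak at either age was found for 141 of 180 chemosensory and 13 of 24 testis and germline genes. The medians of both lists were therefore 0 whatever the other members did, and the means rest on those other members alone. With -log10 q of at least 5 the chemosensory mean was positive (0.00562, percentile 0.06). The testis mean came inside the range with end windows (0.286, percentile 14.5), with -log10 q of at least 5 (0.000914, percentile 4.65) and with the upper 50% of each list (-0.389, percentile 4.81). Examples were Or45b (44.4% and 25.7%), Gr22e (19.5% and 2.95%), can (19.6% and 6.98%) and bol (28.5% and 21.4%), and in the other direction twe (14.0% and 19.2%) and ocn (9.68% and 14.1%).

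Innate immunity genes were above their random lists for H3K27ac by the mean alone. Of 39 genes, 18 had a higher share at day 50 and 7 a lower one, with a mean difference of 4.52, above all 10000 random lists. This mean was 2.78 with the upper 50% of each list (percentile 98.8) and 10.3 with gene bodies alone. The median was 0 (percentile 43.5), and 14 members had no peak at either age. The pattern recognition gene PGRP-SD had no peak at day 10 and 29.6% at day 50, and PGRP-SA had 6.09% and 28.1%. The Imd pathway genes Rel (23.1% and 47.2%) and pirk (4.96% and 25.7%) differed in the same direction.

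The other 14 lists lay inside their random ranges for H3K27ac. Higher and lower genes numbered 70 and 12 for ribosomal proteins, 50 and 20 for oxidative phosphorylation, 25 and 9 for chromatin modifiers, 22 and 3 for oxidative stress and detoxification, 20 and 4 for insulin, TOR and lifespan, 19 and 3 for autophagy, 13 and 5 for circadian clock, and 13 and 4 for heat shock and chaperones. They numbered 10 and 1 for glia, 10 and 8 for phototransduction, 8 and 3 for fat body, 6 and 3 for hemocyte, 2 and 4 for muscle, and 3 and 2 for Hox and segmentation. Random lists matched to the ribosomal, oxidative phosphorylation, stress and autophagy lists also had positive medians, so these counts did not stand apart. In muscle 15 of 21 genes and in Hox and segmentation 19 of 24 had no H3K27ac peak at either age. The medians of these lists were thereby fixed at 0, and their means rest on few genes. Members with large differences were RpL4 (19.2% and 37.5%), ATPsynE (21.1% and 43.5%), COX5A (30.8% and 49.8%), GstE9 (31.2% and 52.3%), Cyp6g1 (4.34% and 20.6%), and Thor, a translation repressor controlled by TOR and foxo (23.1% and 43.6%). Hsp22 (21.7% and 41.3%) and Hsp26 (24.3% and 40.8%), whose regions overlap, the autophagy gene Atg7 (4.74% and 20.9%), the clock gene cyc (5.97% and 20.5%) and ash2 (20.0% and 37.5%) differed in the same direction, and Gclm (60.1% and 43.4%) and RpL40 (38.8% and 24.4%) in the other.

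Of trr, Lpt, nej and Utx, named by the rule, all but Utx carried both marks at both ages. trr, the H3K4 monomethyltransferase, had 70.2% of its region under H3K4me1 peaks at day 10 and 69.1% at day 50, and 9.19% and 10.2% under H3K27ac peaks. Its partner Lpt had 51.3% and 65.0% for H3K4me1 and 15.7% and 19.0% for H3K27ac. The acetyltransferase gene nej had 43.9% and 41.1%, and 5.18% and 8.39%. The H3K27 demethylase gene Utx had 17.4% and 22.2% for H3K4me1 and no H3K27ac peak at either age.

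Most peaks were found at both ages, and the strongest nearly always. For H3K4me1, 79.4% of day 10 peaks (95% exact interval 79.0 to 79.7) overlapped a day 50 peak by at least 1 base, against a mean of 22.8% over 1000 random placements, and 83.2% of day 50 peaks overlapped a day 10 peak (82.9 to 83.6, random mean 23.8%). For H3K27ac these shares were 76.0% (75.4 to 76.5, random 12.1%) and 80.0% (79.5 to 80.5, random 12.6%). Peaks found at 1 age only numbered 9055 and 7013 for H3K4me1 and 6417 and 5096 for H3K27ac, at days 10 and 50. They were narrower than shared peaks, with medians of 190 to 192 bp against 315 to 344 bp. Their median folds were also lower, for example 2.19 against 2.65 in the day 10 H3K4me1 list. In the weakest 10% of each list by -log10 q between 44.2% and 57.6% of peaks were shared, and in the strongest between 99.6% and 100%.

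**Figure D3:**
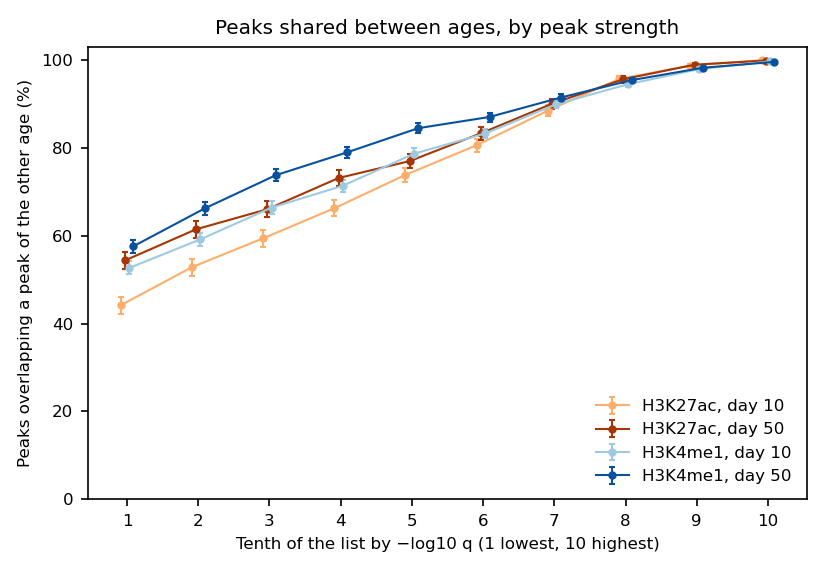
Percent of peaks that overlap a peak of the other age (y axis) in 10 equal parts of a list by -log10 q (x axis), for the 4 lists, with 95% exact binomial intervals as bars. Sharing runs from 44.2% in the weakest part of the day 10 H3K27ac list to 100% in its strongest.

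Peaks lay nearer to gene ends at day 50. Of H3K27ac peaks, 29.5% (29.0 to 30.1) at day 10 and 33.8% (33.2 to 34.4) at day 50 were within 500 bp of a gene end. More than 1000 bp from any gene end there were 16798 peaks at day 10 (62.9%) and 14656 at day 50 (57.6%). These distal peaks covered 5445 kb and 4662 kb, a ratio of 0.856, and the proximal ones 3750 and 4284 kb, a ratio of 1.14. For H3K4me1 the distal share was 67.5% and 64.5%, with covered-base ratios of 0.908 distally and 1.04 proximally. The strongest distal H3K27ac peaks were found at both ages. At day 10 they lay in Sin3A (2R:12589654-12590591, fold 7.09), in the stress-signalling phosphatase gene puc (3R:8112689-8114881, 6.87), near SIFaR (3R:21296701-21297405, 6.81), near CG1888 (2R:9552820-9553383, 6.57) and in ush (2L:481130-482011, 6.41). At day 50 they lay in Xrp1 (3R:18918265-18918670, 7.55, and 3R:18916285-18916934, 6.84), ush (2L:481083-481956, 7.31), near Alp13 (3R:10081490-10083605, 7.08) and in Kr-h1 (2L:6086749-6088414, 6.91).

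The difference between ages varied with gene length. In the longest of 10 groups of genes, from 14.7 kb up, 988 genes had fewer H3K4me1 bases per region at day 50 and 343 more, with a mean of -1.51 percentage points (SEM across genes 0.0856). For H3K27ac 726 had fewer and 456 more, with a mean of -0.99. The group of 4.03 to 6.48 kb had means of 1.95 and 1.94, and the next, up to 14.7 kb, of 1.24 and 1.41. Genes are not replicates, so these errors describe the lists only. Bases near gene ends make up a larger part of the region in short genes. The pattern by length is therefore not independent of the distal and proximal difference above.

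**Figure D4:**
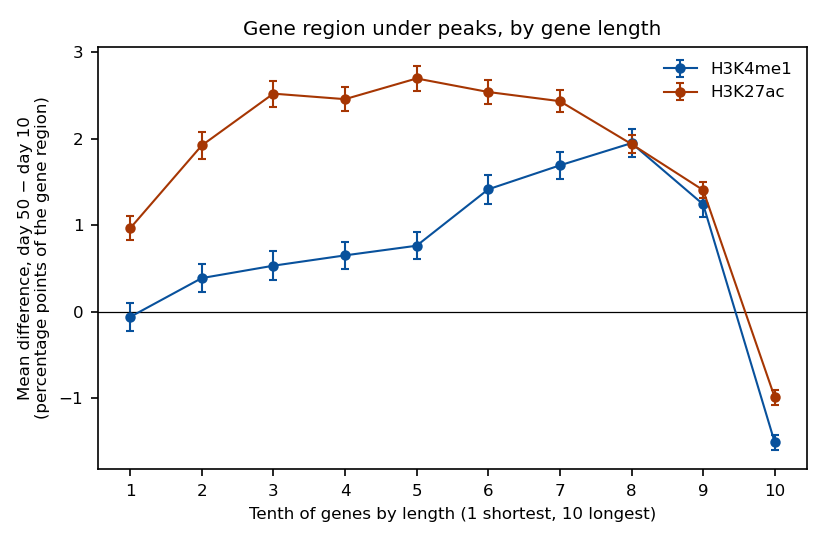
Mean difference between day 50 and day 10 in the percent of the gene region under peaks (percentage points, y axis) for 10 groups of the 13946 genes by length (x axis), with the SEM across genes as bars. The longest group lies at -1.51 for H3K4me1 and -0.99 for H3K27ac, and the group of 4.03 to 6.48 kb at 1.95 and 1.94.

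The X chromosome differed from the autosomes in opposite directions for the marks. Bases under H3K4me1 peaks on X were 2743 kb at day 10 and 2433 kb at day 50, a ratio of 0.887, against 0.963 to 0.998 on 2L, 2R, 3L and 3R. Under H3K27ac peaks X had 1648 and 1722 kb, a ratio of 1.04, against 0.921 to 0.990 on those arms. With the upper 50% of each H3K27ac list, X was no longer apart, at 1.02 times the autosomal ratio (95% block bootstrap interval 0.968 to 1.07).

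**Figure D5:**
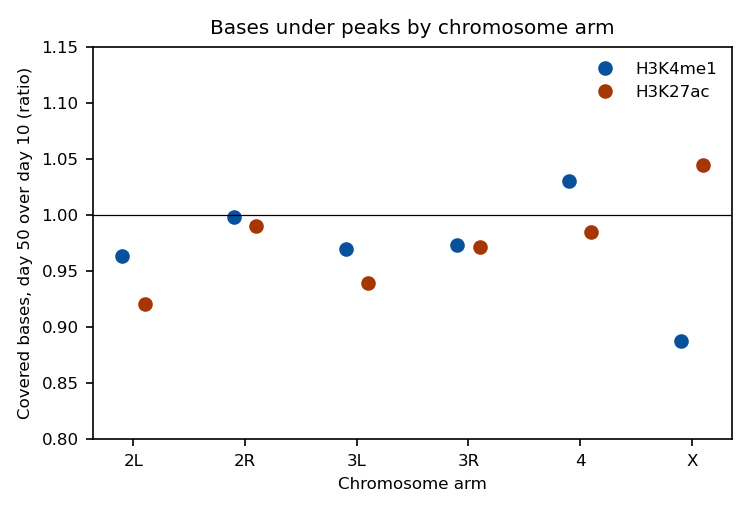
Bases under peaks at day 50 over those at day 10 (ratio, y axis) on each chromosome arm (x axis) for H3K4me1 and H3K27ac, 1 point per pair of lists with no replicate error; the axis does not start at 0. On X the ratio is 0.887 for H3K4me1 and 1.04 for H3K27ac.

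Across the marks, 68.2% of H3K27ac peaks at day 10 (67.7 to 68.8) and 68.4% at day 50 (67.8 to 68.9) lay on an H3K4me1 peak of the same age, against random means of 22.5% and 21.7%. The share was higher for distal peaks (74.1% and 74.5%) than for proximal ones (58.4% and 60.1%). Conversely, 40.2% and 40.1% of H3K4me1 peaks carried an H3K27ac peak. Of the 34808 day 10 H3K4me1 peaks also found at day 50, 12941 carried H3K27ac at both ages, 2390 at day 10 only, 2714 at day 50 only and 16763 at neither. Within 1000 bp of a gene end the day 50 only class was the larger (1323 against 370), and farther away the day 10 only class (2020 against 1391). Across genes, the differences in the marks were weakly related (Pearson's r 0.114, Spearman's rho 0.135 over 13946 genes, which are not independent replicates).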

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

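Signals outside the main chromosomes were picked out by a rule set beforehand, and no explanation of them was tested. Peaks on other sequences of the assembly numbered 8 in the day 10 and 14 in the day 50 H3K4me1 list, and 5 and 7 in the H3K27ac lists, each above the rule's limit of 3. Peaks are calls at a threshold, so passing this limit does not measure the signal on these sequences. Of the H3K4me1 peaks, a scaffold assigned to the Y chromosome carried 1 at day 10, with a fold of 2.86, and 8 at day 50, with a highest fold of 3.08. The main Y sequence carried 0 H3K4me1 peaks at day 10 and 1 at day 50, and 2 and 0 H3K27ac peaks.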

How the results depend on the processing

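No paired analysis was possible because each peak list pools both replicates of a mark and age and the results come from no test, and for the same reason no replicate could be left out. Chosen after seeing the data were the means of the gene lists, gene bodies alone, the upper 50% of each list for gene lists, the distal shares under each setting and matching in 20 length bins. Of 62 alternative values for shared shares, covered lengths, gene ends and mark overlap, 29 stayed: 24 counts of gene ends, within 1.5 times the count, and 5 ratios of covered length, within an interval from the numbers of peaks. All 30 alternative shares of peaks lay outside the exact interval of the share as deposited. The cause was not tested for any value that moved.

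Shares of day 10 and day 50 peaks found at the other age were, for H3K4me1, 77.1% and 80.5% with -log10 q of at least 5, 74.6% and 78.8% with the upper 50% of each list, 80.8% and 81.2% with equal numbers, 79.9% and 84.0% after merging, and 75.8% and 79.8% with at least 50% of the peak overlapped. For H3K27ac, in the same order, they were 77.6% and 75.7%, 73.6% and 78.3%, 77.6% and 78.1%, 76.6% and 81.3%, and 72.2% and 76.2%, so with the stricter threshold the day 10 share was the higher. The share of H3K27ac peaks on H3K4me1 was 61.3% at day 10 and 60.7% at day 50 with the stricter threshold, 52.8% and 51.5% with the upper 50%, 52.0% and 52.7% with equal numbers, 72.4% and 73.2% after merging, and 59.0% and 59.0% with at least 50% overlapped. The covered length at day 50 over day 10 was 0.989 for H3K4me1 with equal numbers. For H3K27ac it turned from 0.973 to 1.03 with the stricter threshold and to 1.004 with equal numbers.

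Among medians of the gene lists, windows of 1000 bp at both gene ends turned synapse and neuronal excitability for H3K4me1 to 0.175 (its mean to 1.22), and gave 0.2 for muscle, -1.04 for Hox and segmentation, 1.70 for oxidative stress and -1.49 for autophagy, all for H3K4me1, and 0 for neuronal surface recognition in H3K27ac. With -log10 q of at least 5 the H3K4me1 medians of fat body, oxidative stress and ribosomal proteins were 0, and the H3K27ac median of circadian clock genes was 3.67, above the random range. With equal numbers testis and germline had 0.0273 for H3K4me1. With the upper 50% the H3K4me1 medians were 0 for oxidative stress, -0.103 for ribosomal proteins and -2.10 for autophagy, and surface recognition had 0 for H3K27ac. With gene bodies alone they were 0 for fat body and 0.385 for oxidative stress, and oxidative phosphorylation had 0 for H3K27ac. Of the 35 alternative medians of the 7 lists outside the random range, 24 kept their side and stayed outside, and of the 50 alternative means of the 10 lists, 43. The means that came inside were, with the upper 50%, 1.90 for fat body and -0.705 for ribosomal proteins in H3K4me1 and -0.389 for testis and germline in H3K27ac, which had 0.286 with end windows and 0.000914 with the stricter threshold, and with gene bodies alone -1.35 for oxidative phosphorylation in H3K4me1. Other medians and means stayed outside the random range but differed more than 1.5 times from the value as deposited. Those of synapse and surface recognition genes with end windows stand beside the results. With the stricter threshold they were, in H3K27ac, a median of -0.355 and a mean of -1.602 for surface recognition, -0.400 and -0.791 for synapse genes and a mean of 0.00562 for chemosensory receptors, and in H3K4me1 a mean of -0.998 for ribosomal proteins. With the upper 50% they were -0.911 and -1.75 for surface recognition, a median of 0.142 for fat body and a mean of -2.002 for oxidative phosphorylation in H3K4me1, and means of -1.14 for surface recognition, 2.78 for innate immunity and -0.195 for chemosensory receptors in H3K27ac. With equal numbers surface recognition had a median of -0.356 in H3K27ac. With gene bodies alone ribosomal proteins had -2.71 and -4.999 in H3K4me1, and innate immunity and testis had means of 10.3 and -1.10 in H3K27ac. The unknown read depth limits every comparison of list length.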

Other observations

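Chosen only after the results were seen were the tests of thresholds and of cell types for the neuronal lists and both tests of distal H3K27ac peaks, while the tests of gene length and of the X chromosome were fixed before their results were known. All observations here come from 1 list per mark and age.

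Several lists differed between the marks, among them ribosomal protein genes. Of the 79 ribosomal members with a difference in both marks, 41 (51.9%) had fewer H3K4me1 bases and more H3K27ac bases at day 50, against 2798 of 8888 genes overall (31.5%). Shares of at least 40% were also found for insulin, TOR and lifespan (11 of 24, 45.8%), autophagy (10 of 22) and glia (5 of 11, 45.5% each), oxidative phosphorylation (29 of 70, 41.4%) and Hox and segmentation (2 of 5, 40%). The pattern was thus not seen in ribosomal genes alone, though some of these counts are small and no difference between lists was tested. The share over all genes is not matched on coverage, and in H3K27ac alone the median of this list (2.42) was below that of its matched random lists (3.34). Of the 42 genes of neuronal surface recognition with a difference in both marks, 29 had fewer bases in both at day 50, against 1515 of the 8888. That comparison is not matched on gene length. In the longest of 10 groups of genes, 988 had fewer H3K4me1 bases and 343 more, and 726 had fewer H3K27ac bases and 456 more.

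A part of the peaks found at 1 age lay beside a peak of the other age, though no chance share was computed for this. Within 500 bp of one were 39.9% and 43.6% of the H3K4me1 peaks found only at day 10 and only at day 50, and 36.6% and 43.7% of the H3K27ac peaks. Random placements of all peaks, without the added 500 bp, already overlapped one in 22.8% and 23.8% (H3K4me1) and 12.1% and 12.6% (H3K27ac). Some of this nearness may thus be chance. Among the strongest peaks without overlap, those inside genes, chosen after their values were seen, lay in eIF4EHP (fold 4.14) and wdb (4.03) for H3K4me1 at day 10 and in AGO2 (3.92) at day 50. For H3K27ac they lay in ASPP (3.85), Liprin-gamma (3.74) and tadr (3.71) at day 10, and in lama and the overlapping CG46456 (4.05), Tsp42Eg (4.04) and RfC4 (4.01) at day 50.

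The synapse and surface recognition lists, but not phototransduction in H3K27ac, had fewer bases under peaks at day 50 in both marks, while in windows at gene ends the synapse list had a median of 0.175 and a mean of 1.22 in H3K4me1. After matching in 20 length bins the highest percentile of medians and means was 1.74. This argues against gene length alone only as far as the bins resolve it. The finer bins lowered the random means, in H3K4me1 from -0.275 to -1.01 for surface recognition and in H3K27ac from 1.03 to 0.0175 for synapse genes. Length thus goes with part of the difference, and lengths within the top bin, which has no upper limit, stay unmatched. Except for surface recognition in H3K27ac, stricter or equally long lists did not remove the difference, with a highest percentile of 0.44 over 3 settings. These settings filter called peaks and cannot restore peaks missed at 1 age. They therefore cannot decide whether the calling threshold or depth contributed. In the exception, the median went from -0.576 to 0 (percentile 50.0) with the upper 50% of each list. There 18 members had no peak against 9 as deposited, while the mean stayed below all random lists. For a lower share of neuronal nuclei alone, the prediction was that other cell types would differ alike. In H3K4me1 the 11 fat body genes with a peak exceeded the 34 of glia, muscle and hemocyte by 8.32 points (95% bootstrap interval over genes 4.41 to 12.7). This cannot decide the question, since a list may shift more where its peaks lie nearer the threshold, and genes are not replicates. With the upper 50% of each list the fat body mean was 1.90, inside the random range (percentile 84.5). A higher share of fat body nuclei, or a difference of age within neurons, may also contribute, and neither was tested. All 3 stay open with 1 list per age.

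H3K27ac peaks were less often distal at day 50. With -log10 q of at least 5 the difference in the distal share was -4.25 percentage points, and with equal numbers of peaks -4.4. It was -6.37 with the upper 50% of each list and -4.06, the closest to 0 of the 4 settings, after merging. Such filters thus did not remove the difference. They act on called peaks and cannot restore peaks missed at 1 age, so they cannot decide whether the calling threshold contributed. Higher enrichment or depth at day 50 would add distal bases, and their ratio was 0.856 (block bootstrap interval 0.838 to 0.875). That prediction was written after the results were seen, and the ratio is part of the pattern itself, so it cannot decide the question. The interval covers blocks of the genome in a single pair of lists, and read depth was unknown. A lower sensitivity for weak, mostly distal peaks combined with better signal at gene ends was not tested, and an effect of age may be involved but was not tested either.

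On X, H3K4me1 covered fewer and H3K27ac more bases at day 50 relative to the autosomes. A few regions of X are argued against by intervals over 1-Mb blocks: the X ratio over the autosomal ratio was 0.908 (0.885 to 0.930) for H3K4me1 and 1.09 (1.05 to 1.14) for H3K27ac. For H3K4me1 the value closest to 1 under stricter or equal lists was 0.912 (0.887 to 0.934), so such filters did not remove the difference. These settings filter called peaks and do not equalise read depth, which was unknown. A difference in depth that weighs otherwise on X than on the autosomes therefore cannot be told apart from one on X. For H3K27ac the value closest to 1 was 1.02 (0.968 to 1.07), which stays above 1, the criterion written beforehand. Its interval, considered only after the value was seen, includes 1, so a difference in weak peaks cannot be told apart from one on X. A chromosome-specific effect of age may exist for H3K4me1 and stays untested.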
